A study of Mus musculus with 6 samples.

How the data were processed

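Reduced representation bisulfite libraries of mouse kidney were analysed from 6 deposited files, 1 per library. Per the labels' protocols, DNA was digested with MspI, end-repaired and adenylated with a nucleotide mix that held methylated dCTP, ligated to methylated adapters, selected for inserts of 40 to 120 and 120 to 220 bp, converted with bisulfite and amplified. The submitters' processing notes name Bowtie and the genome build mm9, with no version; trimming, methylation caller and filters are not given in the sources used here. The files carry no header, so the meaning of their columns was worked out from the values. Each row is a CpG site with its position, a strand sign, and deposited counts of covering reads and of methylated reads. The fraction that the authors deposited beside them equals methylated over covering reads to the decimals given in every row. Positions were taken as 0-based starts and are printed 1-based, and no position occurred more than once in a library. The largest position on chromosome 1, 197193420, was the same in all 6 libraries.

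Libraries were grouped by the treatment given in the labels: saline-treated obstruction, sham, and 5AZA-treated obstruction, with 2 libraries each. Sham 2 was labelled as the sham of another injury model and was kept in the sham group because its treatment label is sham. Sites covered at least 10 times in all 6 libraries were used. Global levels are means over these sites of each library's methylation percent, compared by an exact two-sided permutation test. Sites were also split into 7 classes by their mean level over the 6 libraries, and windows by their number of CpG sites.

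Methylated and unmethylated read counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest). The model had an intercept per library and a group effect on the methylated counts, all 6 libraries shared one common dispersion, and p-values were adjusted by Benjamini-Hochberg. Tests were run per CpG site (920122 sites, leaving out those fully methylated or fully unmethylated in all libraries) and on counts summed over windows of 1000 bp with at least 3 sites (89813 windows). The common dispersion was 0.00632 for windows, with 10.4 prior degrees of freedom. Windows were named by a rule: the 5 largest rises and the 5 largest falls among windows past an adjusted p of 0.05 whose libraries did not overlap between groups, filled up by the smallest p. These choices were made before the data were examined.

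The design also planned tests of promoters, gene bodies and gene lists. They need gene positions on mm9. The table of gene names at hand is of GRCm38.p6 and holds neither strands nor sequence, and positions were not converted between builds, so these tests were not run and windows are given by coordinate without gene names. The edgeR tests of sites and windows between saline and sham were tested on simulated data. With 100 windows changed for each size in a set of 89812, the window test recovered 16% of changes of 10 percentage points and 62% of changes of 20 points, with 2 calls among unchanged windows. Among 92854 sites the site test recovered 0% and 2%. In 10 simulations of unchanged groups, each comparison had at most 1 window called. All these simulations gave every window and library the same spread, so they hold no library that stands apart as sham 2 did. The other fits were not tested for recovery.

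Alternatives were a coverage minimum of 5 or 20, leaving out the most deeply covered 0.1% of sites in any library, limma 3.58.1 on log2 ratios of methylated to unmethylated counts with 1 added to each, Fisher's exact test on pooled counts, autosomes only, windows of 500 bp, at least 5 sites per window, a minimum difference of 10 points, only the 4 libraries of the groups compared, a replicate block, and leaving out each library in turn. Where a left-out library leaves a group with 1, that library is assumed to vary like the others. Alternatives without candidate fragment-end sites, without windows or sites under a mean level of 20%, with fixed read weights, and with the dispersions of the window fits with and without candidate fragment-end sites exchanged were added after the data were seen. A site was a candidate fragment end when its coverage lay within 5% of the sum of both neighbours' coverage, each within 220 bp and with at least 10% of it. A mean level of at least 30% in a 1 kb window of at least 10 sites with a median under 5% also qualified. Coverage counts reads rather than molecules, since no molecular identifiers are described. Tables were handled with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and numba 0.67.0.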

Results

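DNA methylation was measured by reduced representation bisulfite sequencing in kidney cortex and outer medulla of male C57BL/6J mice. This assay digests DNA with MspI, which cuts at CCGG, keeps short fragments and reads each cytosine after bisulfite treatment, so that it samples CpG-rich parts of the genome. The 6 libraries formed 3 groups of 2: kidneys obstructed by ligation of the left ureter for 7 days with saline injection (UUO, saline), sham-operated kidneys, and obstructed kidneys of mice given the drug that the labels call 5AZA at 1 mg/kg per day (UUO, 5AZA). The obstructed kidney is a standard model of renal fibrosis. Sham 1 was the sham for the obstruction model, whereas sham 2 was labelled as the sham of an ischemia/reperfusion experiment, with a time of 48 hours in its name instead of 7 days.

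Covering reads summed over CpG sites came to 76730132 and 65733691 in the saline libraries, 68501854 and 37728517 in sham 1 and sham 2, and 57853745 and 64539660 in the 5AZA libraries. Median coverage per site was 48 and 37 reads in saline, 37 and 21 reads in sham, and 36 and 33 reads in 5AZA. Of 2134823 CpG sites seen in any library, 943307 were covered at least 10 times in all 6. Libraries of the same group differed by more than sampling noise, taken as if each read were a separate molecule, so amplification may add to the excess. At sites of intermediate level, without candidate fragment-end sites, the squared difference between replicates was 1.38 times its sampling variance in saline, 1.68 times in sham and 1.31 times in 5AZA. For pairs from different groups it ranged from 1.47 times (sham 1 and 5AZA 1) to 2.28 times (saline 1 and 5AZA 2). Some such pairs thus had a lower ratio than the 2 sham libraries. Sampling variance shrinks with coverage, so the ratio rises with coverage where libraries truly differ. Pairs of unlike coverage are therefore not strictly ranked by it. The labels do not say that the libraries came from separate mice, so the p-values measure the spread between these samples, which may be technical in part. The first principal component of the site levels (31.3% of the variance) set sham 2 apart from the other 5 libraries. The second (22.7%) placed both saline libraries at one end and both 5AZA libraries at the other.

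CpG-rich windows held sites of sharply different level side by side. In windows of 1 kb whose median level was under 5%, 84822 of 475180 CpG sites (17.9%) nevertheless had a mean level of at least 30%. These sites averaged 74.3% and 74.5% in the saline libraries, 73.0% and 69.3% in sham 1 and sham 2, and 73.1% and 73.2% in the 5AZA libraries, while the other sites of the same windows averaged 1.05% to 2.29%. They lay a median of 88 bp apart, and 81.7% of their spacings fell within the 40 to 220 bp selected as inserts. Such sites, together with sites whose coverage equalled the summed coverage of both neighbours, are called candidate fragment-end sites; they made up 12.8% of all sites and 53.5% of those with a mean level of 60 to 80%.

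**Figure D1:**
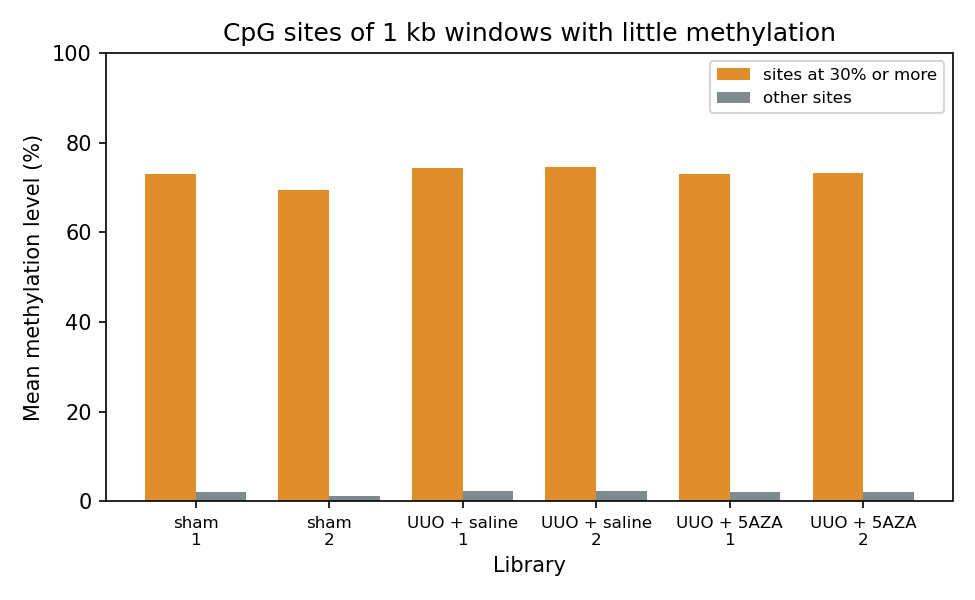
Mean methylation level (%) in each of the 6 libraries of the CpG sites in 1 kb windows with a median level under 5%. Orange bars are the 84822 sites with a mean level of at least 30% and grey bars the 390358 other sites; the first lie between 69.3% and 74.5% in every library, and the others between 1.05% and 2.29%.

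The first comparison asked which parts of the kidney genome changed in methylation after 7 days of obstruction. CpG sites of intermediate level were more methylated in both obstructed saline kidneys than in both sham kidneys. At the 21103 sites with a mean level of 20 to 40% over the 6 libraries, the level was 34.3% in each saline library, 28.95% in sham 1 and 25.9% in sham 2, a difference of 6.88 percentage points between group means and of 5.37 points against sham 1 alone. At 29736 sites of 40 to 60%, the means were 55.4% ± 0.039 (SD, n = 2) in saline and 49.6% ± 3.47 (SD, n = 2) in sham, a difference of 5.76 points, of which 3.31 were left against sham 1 alone. At 60 to 80% the difference was 3.44 points, and 1.53 against sham 1 alone. Candidate fragment-end sites, 53.5% of this class, differed by 3.32 points and its other sites by 3.58, so both kinds moved alike. At 126284 sites of 95% or more saline and sham were nearly equal, at 97.9% ± 0.0086 and 97.8% ± 0.048 (SD, n = 2 each). Sites under 5% averaged 1.84% ± 0.026 in saline and 1.14% ± 0.61 in sham (SD, n = 2 each), of which sham 2 gave 0.71% and sham 1 gave 1.56%.

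Averaged over all 943307 sites, the methylation level was 45.3% ± 0.029 in saline and 43.7% ± 1.06 in sham (SD, n = 2 each), a difference of 1.61 points. The difference was positive on 19 of 19 autosomes, from 1.47 to 1.76 points, and was 1.28 points on the X chromosome. Autosomes share the level of their library, so they add no replicates. The exact two-sided permutation test gave p = 0.33, the smallest value that 2 libraries against 2 allow. Sham 2, at 42.9%, lay below sham 1, at 44.4%; without sham 2 the difference was 0.865 points, and without sham 1 it was 2.36 points. As methylated reads over all reads at the same sites, the difference was -0.0686 points. The share of reads at sites of 80% or more ranged from 26.0% to 30.1% between libraries, and with each site's read weight held equal in all libraries the difference was 1.56 points. Without candidate fragment-end sites all levels were lower, at 40.9% and 41.0% in saline and 40.1% and 38.9% in sham 1 and sham 2. The difference was then 1.42 points.

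**Figure D2:**
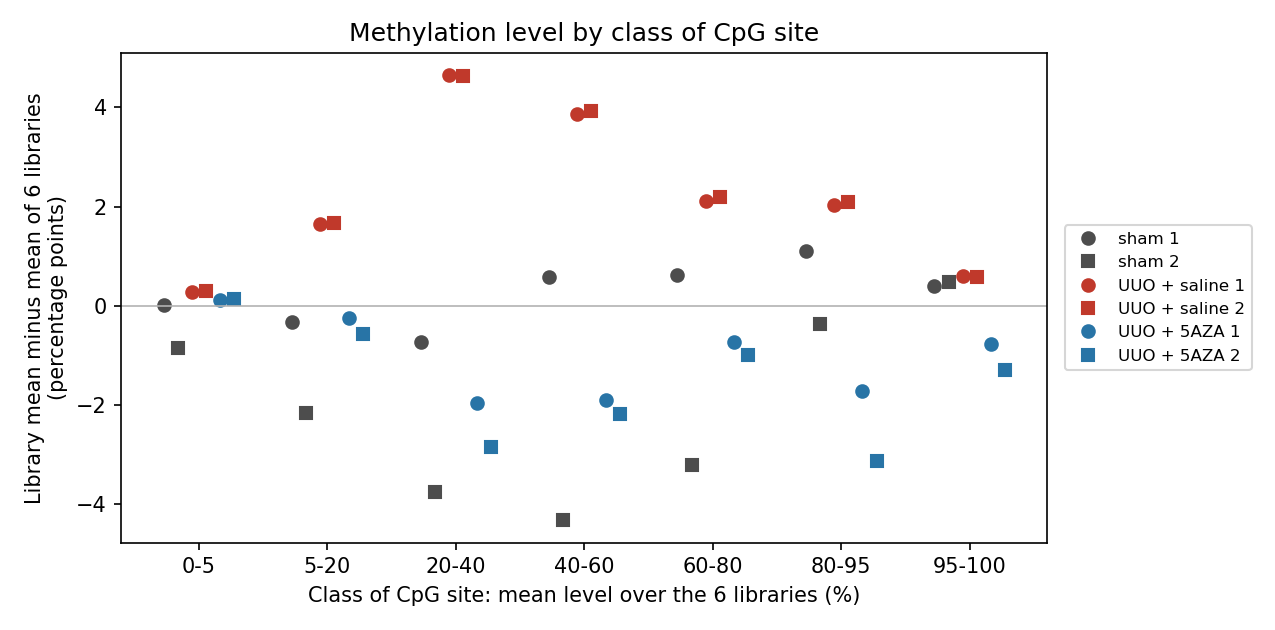
Mean methylation level of each library minus the mean of the 6 libraries (percentage points, vertical axis) in 7 classes of CpG site by their mean level over the 6 libraries (%, horizontal axis). Circles are replicate 1 and squares replicate 2 of sham (grey), UUO with saline (red) and UUO with 5AZA (blue). Saline libraries lie highest in every class; at 20 to 40% the saline mean was 6.88 points above the sham mean, and at 80 to 95% the 5AZA mean differed from the saline mean by -4.47 points.

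In windows of 1 kb with at least 3 CpG sites, 45 of 89813 differed between saline and sham (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05), 40 of them higher and 5 lower after obstruction. The called windows had a median of 14 CpG sites, and 37 of the 45 had a mean level of 20 to 80%. The 40 rising windows averaged 60.3% ± 0.19 in saline, 42.6% ± 1.96 in sham and 48.1% ± 0.52 in 5AZA (SD, n = 2 each). Both saline libraries lay above both sham libraries in 32.3% of all windows and below both in 9.73%. Chance gives 16.7% for either order only if all 4 libraries are alike in overall level. Sham 2 lay lower as a whole, so these shares do not separate obstruction from sham 2.

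The largest rise among called windows was on chromosome 8 at 13248001 to 13249000 (mm9, as are all positions here; 6 CpG sites, 233 to 560 reads per library), from 41.2% ± 7.91 in sham to 69.8% ± 3.11 in saline (SD, n = 2 each; edgeR adjusted p = 0.0438). Next came chromosome 10 at 79279001 to 79280000 (8 sites, 105 to 277 reads), with 61.1% ± 9.03 in sham and 88.9% ± 2.15 in saline (edgeR adjusted p = 0.0419), and chromosome 17 at 44272001 to 44273000, with 51.5% and 79.1% (edgeR adjusted p = 0.0438). Chromosome 6 at 134199001 to 134200000 rose from 52.1% ± 1.87 to 78.6% ± 2.67 (edgeR adjusted p = 0.0277), and chromosome 3 at 104467001 to 104468000 from 60.8% to 86.8% (edgeR adjusted p = 0.0447). The largest fall was on chromosome 15 at 79891001 to 79892000 (4 sites, 102 to 279 reads), from 91.1% ± 0.14 in sham to 64.0% ± 0.29 in saline (edgeR adjusted p = 0.0425). The other falling windows, on chromosome 10 at 77623001 to 77624000, chromosome 11 at 87570001 to 87571000, chromosome 5 at 92747001 to 92748000 and chromosome 16 at 36709001 to 36710000, differed by -16.4, -15.9, -12.7 and -9.14 points. Each of these 10 windows kept its direction under every alternative that could be computed for it, but their adjusted p-values ranged from 0.0102 to 0.45.

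Most windows called without sham 1 or without saline 2 were not among the 45, and the call count rested on few libraries. It was 0 without saline 1 (5805 windows at an unadjusted p under 0.05), 7 without saline 2, 40 without sham 1 and 1 without sham 2, and limma on log2 ratios called 0 (9756 unadjusted), against 9372 unadjusted with all libraries. With windows of a mean level of at least 20% alone, chosen after the data were seen, it was 2, and without candidate fragment-end sites it was 0 (8379 unadjusted). All 45 windows kept their direction without these sites, and the mean size of their difference was 18.4 points, against 17.6 with them; 17 of the 45 held no such site, and at a mean level of at least 20% the counts of a window did not change at all. Single CpG sites gave 26 calls of 920122 tested, 19 higher and 7 lower; 14 of these were among the most deeply covered 0.1% of sites, and 2 calls were left when those sites were not tested. Site counts were 3 without saline 1, 14 without saline 2 and 208 without sham 1.

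The second comparison asked what 5AZA changed in obstructed kidneys. Mean methylation was lower in both 5AZA libraries than in both saline libraries in each of the 7 classes of site, the most highly methylated included. At 187527 sites with a mean level of 80 to 95%, the level was 91.0% ± 0.041 with saline and 86.5% ± 0.99 with 5AZA (SD, n = 2 each), a difference of -4.47 points; sham had 89.3% ± 1.04 (SD, n = 2). At sites of 95% or more it was 97.9% with saline and 96.3% ± 0.36 with 5AZA (SD, n = 2), a difference of -1.62 points. Sites of 20 to 40% went from 34.3% with saline to 27.3% ± 0.62 with 5AZA (SD, n = 2), a difference of -7.04 points. Under 5%, the difference was -0.17 points.

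Over all shared sites the level was 43.3% ± 0.30 with 5AZA, -2.04 points from saline (SD, n = 2; exact two-sided permutation p = 0.33, the smallest possible). The difference was negative on 19 of 19 autosomes, from -2.19 to -1.87 points, and was -1.80 points on the X chromosome. These autosomes, and the bins that follow, share the level of their library and add no replicates. In windows of 80% or more grouped into 514 bins of 5 Mb with at least 20 windows each, both 5AZA libraries lay below both saline libraries in 514 bins; the median difference was -3.90 points and the range -5.74 to -2.70. Counted as methylated reads over all reads, the global difference was 0.819 points, and -1.89 points with each site's weight held equal. Over every site that each library covered at least 10 times, it was -1.02 points. Without candidate fragment-end sites the 5AZA libraries averaged 39.1% and 38.6%, and the difference from saline was -2.09 points.

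In 1 kb windows, 1396 differed between 5AZA and saline (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05): 1392 were lower with 5AZA and 4 higher. Of the 1396, 1084 had a mean level of 80% or more, and 555 differed by at least 10 points. Both 5AZA libraries lay below both saline libraries in 49.1% of all windows, and above both in 5.69%. Chance gives 16.7% for either order only if all 4 libraries are alike in overall level. Since both 5AZA libraries lay lower as a whole, these shares do not separate changes of single windows from a shift of whole libraries. The mean difference was -3.98 points in windows of 3 or 4 CpG sites, -1.49 points at 10 to 19 sites and 0.0412 points at 40 or more, where the mean level with saline was 15.0%. Among windows of 80% or more alone, it was -3.76 points at 3 or 4 sites and -3.72 points at 10 to 19.

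The largest falls with 5AZA were on chromosome 12 at 13191001 to 13192000 (5 CpG sites, 50 to 184 reads per library), from 84.8% ± 3.89 to 53.9% ± 3.70 (SD, n = 2 each; edgeR adjusted p = 0.0314), and on chromosome 9 at 114625001 to 114626000 (5 sites, 149 to 325 reads), from 69.0% ± 2.12 to 38.3% ± 2.09 (edgeR adjusted p = 0.0204), with sham at 51.6%. Chromosome 4 at 131358001 to 131359000 and at 83842001 to 83843000 fell by 28.2 and 28.1 points, and the chromosome 10 window at 79279001 fell by 27.8 points to the sham level of 61.1%. The 4 rising windows were chromosome 8 at 24319001 to 24320000 (20.3% with saline, 36.2% with 5AZA, 35.2% in sham), chromosome 4 at 53727001 to 53728000 (18.97%, 31.4% and 16.3%), chromosome 4 at 133428001 to 133429000 (78.4%, 89.8% and 89.6%) and chromosome 14 at 20597001 to 20598000 (82.8%, 93.1% and 93.3%). Chromosome 11 at 119490001 to 119491000 was 13.0 points higher with 5AZA and did not pass (edgeR adjusted p = 0.0512). The rise on chromosome 8 was 2.92 points at a coverage minimum of 20 and 4.75 points without the most deeply covered sites. None of these 10 windows reversed under an alternative; their adjusted p-values ranged from 6.7e-05 to 0.317.

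The count of 1396 was 0 without saline 1 or without saline 2 (14112 and 15550 windows at an unadjusted p under 0.05), 4 without 5AZA 2 and 1180 without 5AZA 1. Most windows called without 5AZA 1 were not among the 1396. By limma the count was 0 (18379 unadjusted, against 20851 by edgeR), in the 4 libraries of both groups alone 173, and without candidate fragment-end sites 0 (17679 unadjusted). Leaving out windows under 20% as well gave 1409. Of the 1396 windows, 1370 could be tested without these sites and 1370 kept their direction, with a mean size of 10.3 points against 9.94 with them, and 771 held no such site. Site calls numbered 15 (14 lower, 1 higher), 10 of them among the most deeply covered 0.1% of sites, without which 3 were left. They were 2 and 6 without saline 1 and saline 2, 9 without 5AZA 1 and 43 without 5AZA 2.

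Windows that rose with obstruction were lower again with 5AZA. Of the 40 rising windows, 27 also fell with 5AZA at an adjusted p under 0.05, where independent lists would share 0.62, and 1.49 would be shared if these windows fell as often as all windows of the same class of mean level and CpG number. All 45 windows called after obstruction had a 5AZA difference of opposite sign. The saline libraries enter both comparisons, and in 10 simulations of unchanged groups with a common saline group 96.9% of the 45 top windows had opposite signs on average. Over all windows, both differences correlated at r = -0.522, against -0.475 in the simulations. Over all 45 windows, the 5AZA difference was 0.647 of the size of the obstruction difference, against a mean of 0.456 and a maximum of 0.528 over the top 45 windows of the simulations. The simulations hold no general loss with 5AZA, and they give all windows and libraries the same spread. The ratio was 0.691 in the 40 rising windows and 0.271 in the 5 falling ones. The rising windows differed by -12.2 points with 5AZA on average, against -3.29 points in all windows of the same classes. Only 2 saline libraries exist, so splitting them leaves 1 for each comparison. When saline 2 was kept out of the choice of windows, 35 of the 36 rising windows among the top 45 were lower with 5AZA than in saline 2, by a mean of -6.69 points; windows of the same classes at large would give 28.3 of 36 and -4.06 points. With saline 1 kept out, 36 of 39 were lower, by a mean of -10.4 points, against 28.5 and -3.78 points. In these choices only 7 and 0 windows were called. These windows inherit the limits on the calls given above, and part of the excess may come from the shared saline libraries.

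**Figure D3:**
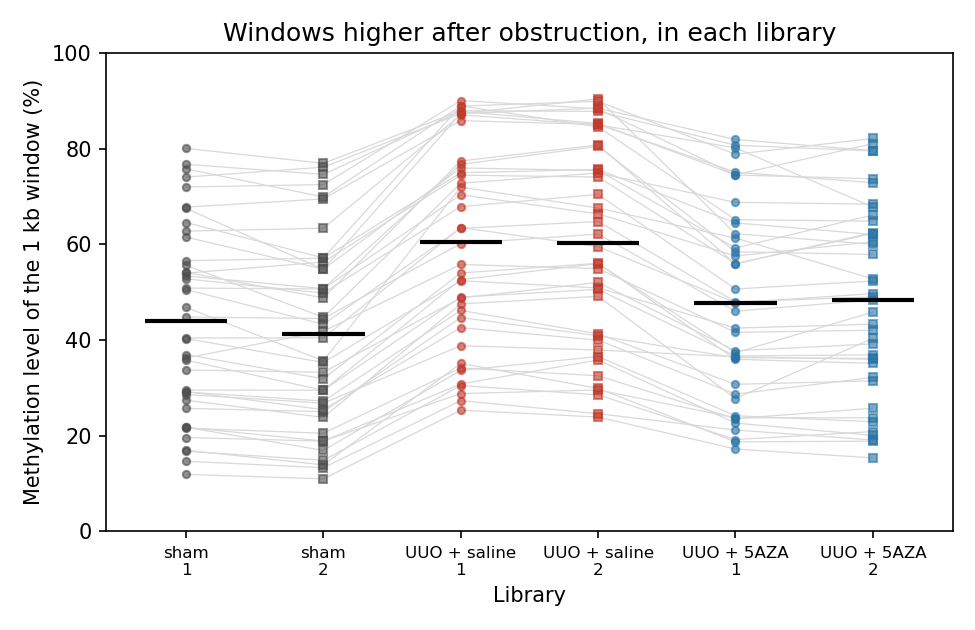
Methylation level (%) of the 40 windows of 1 kb called higher in obstructed saline than in sham kidneys, in each of the 6 libraries. Each point is a window, grey lines join the same window, and black bars are the mean per library. The windows were selected for the saline to sham difference (60.3% against 42.6%); the 5AZA mean was 48.1%.

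The series title concerns Hoxa5, a homeobox transcription factor gene that lies on chromosome 6. On that chromosome lay 3 of the 27 windows that rose with obstruction and fell with 5AZA. Of these 3, the one richest in CpG sites, at 52154001 to 52155000 (45 sites, 1539 to 3729 reads per library), was singled out after its values were seen. Its level was 20.3% ± 2.04 in sham, 33.3% ± 3.55 with saline and 21.3% ± 1.82 with 5AZA (SD, n = 2 each; edgeR adjusted p = 0.0419 for obstruction and 0.0266 for 5AZA). Over the alternatives, these adjusted p-values ranged from 0.0265 to 0.432 and from 0.00035 to 0.178. Without an mm9 gene annotation, its place relative to that gene was not determined, so these values are no evidence on Hoxa5.

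The third comparison set 5AZA-treated obstructed kidneys against sham kidneys. At intermediate sites the group means were close with both sham libraries, while 5AZA was lower at highly methylated sites and slightly higher at sites under 5%. Under 5%, both 5AZA libraries (1.66% and 1.68%) lay above sham 1 (1.56%) and sham 2 (0.71%), a difference of 0.536 points between group means and of 0.108 against sham 1 alone. Levels at 20 to 40% were 27.3% ± 0.62 with 5AZA and 27.4% ± 2.15 in sham, and at 40 to 60% they were 49.4% ± 0.20 and 49.6% ± 3.47 (SD, n = 2 each). Against sham 1 alone, both 5AZA libraries were lower in these classes, with mean differences of -1.68 and -2.62 points, and without candidate fragment-end sites the difference from both sham libraries at 40 to 60% was -1.29 points. At 80 to 95% both 5AZA libraries (87.2% and 85.8%) lay below both sham libraries (90.01% and 88.5%), and at 95% or more the difference was -1.47 points. Over all sites it was -0.432 points (exact two-sided permutation p = 1). That value changed sign without sham 1 (0.314 points), as methylated reads over all reads (0.75 points) and over every site covered at least 10 times per library (0.362 points), so it gave no direction. With both sham libraries it was still negative on 19 of 19 autosomes, from -0.555 to -0.209 points. Counts of autosomes thus follow the library means and give no separate evidence in any of the comparisons.

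A single window differed in this comparison (edgeR quasi-likelihood test, Benjamini-Hochberg), with 1283 higher and 11939 lower at an unadjusted p under 0.05. It lay on chromosome 8 at 46095001 to 46096000 (14 CpG sites, 318 to 1493 reads per library), with 99.0% ± 0.26 in sham, 97.8% ± 0.36 with saline and 92.2% ± 0.94 with 5AZA (SD, n = 2 each; edgeR adjusted p = 0.0146). Its adjusted p ranged from 0.00838 to 0.259 over the alternatives. The lower windows next in order did not pass: chromosome 15 at 93331001 to 93332000, chromosome 3 at 153234001 to 153235000, chromosome 12 at 30687001 to 30688000 and chromosome 4 at 131456001 to 131457000 differed by -5.95, -18.8, -3.32 and -3.66 points (edgeR adjusted p = 0.068 each); the chromosome 15 difference was -3.92 points at a coverage minimum of 20. Nor did the higher ones, which were chromosome 4 at 53727001 to 53728000 (15.1 points), chromosome 7 at 150645001 to 150646000 (8.53), chromosome 10 at 62443001 to 62444000 (6.38, and 1.60 without candidate fragment-end sites), chromosome 1 at 193759001 to 193760000 (16.6) and chromosome 2 at 29337001 to 29338000 (18.4), with adjusted p from 0.0901 to 0.122 by edgeR. The window count was 2 without sham 1, 6 without sham 2 and 148 without 5AZA 1. By limma it was 0 (12357 unadjusted), and without candidate fragment-end sites 0 (11870 unadjusted), although the called window held none of these sites and kept its difference of -6.81 points (adjusted p = 0.225). Site calls numbered 14 (3 higher, 11 lower), 10 of them among the most deeply covered 0.1%, without which 1 was left. They were 106 without sham 1, 30 without sham 2, and 6 without 5AZA 1.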

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

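Of the settings below, those on candidate fragment-end sites, a mean level of at least 20%, fixed read weights, exchanged dispersions and read shares without the most covered sites were chosen after seeing the data. Named windows kept their direction in every alternative computed. The common dispersion for windows was 0.00632 with all sites, 0.0187 without candidate fragment-end sites and 0.0119 when windows under 20% were left out as well. Values below are in the order saline vs sham, 5AZA vs saline, 5AZA vs sham unless a comparison is named, and where no cause is given the cause was not tested.

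Global differences as methylated reads over all reads were -0.0686, 0.819 and 0.75 points, and 0.0376, 0.868 and 0.906 points without the most covered sites; with fixed read weights they were 1.56, -1.89 and -0.339, so the reversal came from how reads were spread over sites. Over every site of each library, 5AZA vs saline was -1.02 and 5AZA vs sham 0.362 points. At a coverage minimum of 20, 5AZA vs saline was -1.80 points. Leaving out each library gave 0.865 to 2.36, -2.25 to -1.83, and -1.18 to 0.314 points. Without candidate fragment-end sites the global differences were 1.42, -2.09 and -0.669 points.

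Site calls were 2, 3 and 1 without the most covered sites, 0, 0 and 0 by limma (67739, 79548 and 57365 at an unadjusted p under 0.05), 14, 8 and 6 without candidate fragment-end sites, 74, 265 and 67 at a mean level of at least 20%, and 11, 74 and 8 in the 4 libraries compared. Pooled Fisher tests, which ignore the spread between replicates, called 3776, 6185 and 1147. With a difference of at least 10 points, 8 and 9 were left in the 5AZA comparisons, and sites of at least 20% without candidate ends gave 63 for 5AZA vs saline. Leaving out each library gave 3 to 208, 2 to 43 and 6 to 106.

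Window calls were 0, 0 and 0 by limma (9756, 18379 and 12357 unadjusted) and 0, 0 and 0 by edgeR without candidate fragment-end sites (8379, 17679 and 11870 unadjusted). Yet 17, 771 and 1 of the called windows held no such site and so kept their counts and differences, so their calls ended through what the fit shares between windows and the adjustment. Dispersion alone was not enough: at that of all sites, the fit without these sites had 0, 0 and 0, and all sites at the larger dispersion had 3, 552 and 1. At a mean level of at least 20%, saline vs sham had 2, and 0 without candidate ends as well (7347 unadjusted). Pooled Fisher tests called 8663, 23348 and 11109. In the 4 libraries compared there were 72 and 173 in the first and second comparison, and in windows of 500 bp 28 and 413. A coverage minimum of 20 left 850 and a difference of at least 10 points 555 for 5AZA vs saline; the latter left 0 of 1 for 5AZA vs sham. Leaving out each library gave 0 to 40, 0 to 1180 and 1 to 148.

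Saline and 5AZA libraries share replicate numbers, and whether these mark pairs was not settled. Over windows, the differences between replicates of the 2 groups correlated at r = 0.0762. Yet a replicate block lowered the common dispersion for windows of these 4 libraries from 0.00476 to 0.00224. It gave 6856 windows (234 higher, 6622 lower) and 23 sites for 5AZA vs saline. The drop in dispersion was not set against that of a block with swapped replicate numbers, so it does not show that the libraries are pairs. Planned promoter, gene body and gene list alternatives, and promoters of at least 1 site, were not run for want of an mm9 annotation. Median coverage was lowest in sham 2, at 21 reads; a coverage minimum of 20 gave 30, 16 and 13 site calls.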

Other observations

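The tests of bisulfite conversion, of sham 1 alone, of candidate fragment-end sites within classes of level and of the mitochondrial fragments were chosen only after the results were seen.

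At 8 of the 10 mitochondrial CpG sites covered, all 4 obstructed libraries had a smaller part of the reads than both sham libraries. In the MspI fragment between CpG sites at 3333 and 3401 of the mitochondrial genome, coverage of the interior sites per 1000000 covering reads was 294 and 336 in sham 1 and sham 2. It was 65.2 and 89.7 in the saline libraries and 69.6 and 140 in the 5AZA libraries. The sham mean was 3.46 times the mean of the 4 obstructed kidneys (exact permutation p = 0.0667, the smallest that 2 against 4 libraries allow). The fragment between 6275 and 6389 gave 229 ± 42.6 in sham (SD, n = 2) and 60.9 ± 50.8 in obstructed kidneys (SD, n = 4), a ratio of 3.76. For 6247 and 4072 nuclear fragments of the same lengths, within 5 bp, the ratios were 0.801 and 1.14. The groups overlapped at 6231 and 6263; at 6231, 5AZA 2 had 35.4 per 1000000 and sham 2 had 27.8. Nuclear copies of mitochondrial sequence were not separated. At position 6231 the level was 54.6% in saline 1 at 291 reads, and 1.53% to 19.3% in the other libraries at 983 to 2750 reads.

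Highly methylated CpG sites stood inside windows with little methylation. Among sites whose coverage was the sum of both neighbours' coverage, 86.3% were at 30% or more, against 11.9% of other sites, a ratio of 7.28; the prediction for fragment ends was written before this test. Incomplete conversion regardless of place in a fragment would give both kinds of site a like share, so the ratio argues against it. A candidate explanation is methylated cytosine filled in at MspI ends during end repair, since the nucleotide mix held methylated dCTP. No biological explanation was tested.

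Sites of 20 to 40% were more methylated after obstruction. Incomplete conversion would add at most as much there as at sites under 5%, but the difference was 6.18 points larger. Candidate fragment-end sites, which were 6.12% of this class, rose by 5.29 points, 0.756 of the 6.99 points at its other sites. Cytosine filled in during library preparation should not change with obstruction. Why these sites rose was not tested, and a shift common to both kinds of site stays open. Against sham 1 alone the rise of the whole class kept 78.0% of its size, but 57.4% at sites of 40 to 60% and 44.3% at 60 to 80%. At 20 to 40%, these values argue against conversion, fragment ends and the sham of the other injury model as the whole cause. At 60 to 80%, candidate fragment-end sites rose by 3.32 points and the other sites by 3.58. There, that sham and a shift common to both kinds of site stay open. A hypothesis is that obstruction may raise methylation at such sites; a change in the cell types of the obstructed kidney stays open and was not tested.

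Sites of 80% or more were less methylated with 5AZA. More complete conversion of unmethylated cytosines would lower sites under 5% by as much, but the loss was 4.31 points larger at 80 to 95% and 1.45 points larger at 95% or more. At candidate fragment-end sites (14.9% and 8.46% of these classes) the loss was 0.775 and 0.960 of that at other sites, so neither fits as the whole cause. Filled-in cytosine should not change with the drug either. Why these sites fell was not tested, and a shift common to both kinds of site stays open. Loss of methylated cytosines to bisulfite would lower all in proportion, but with classes set by sham alone the loss relative to saline was 4.61% (relative SD 1.00%) at 80 to 95% and 2.52% (relative SD 0.617%) at 95% or more, and the excess of 2.08 percentage points argues against it as the whole cause at 80 to 95%. At 95% or more it cannot be told apart from the drug, because the outcome depends on how the class is set. With classes set by the mean of the 6 libraries, the relative loss was 1.65%. That differed by -0.0156 percentage points from the 1.67% at the highly methylated sites in windows with little methylation, which also varied between saline and sham. With the class set by sham alone, the 2.52% given above was larger than at those sites. The loss at 80 to 95% may reflect the drug, as a hypothesis; a change in cell types stays open and was not tested.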
